A study of Mus musculus with 12 samples.

How the data were processed

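The series holds 12 expression arrays of mouse peritoneal macrophages recruited with thioglycollate. Each array stands for 1 of 3 genotypes (wild type, IRAK2 knockout, and the knockout of both IRAK1 and IRAK2, called the double knockout here) at 0, 2, 4 or 8 h of MALP-2 at 100 ng/ml. Per the labels' protocols, RNA was extracted with Trizol and amplified and labelled with the NuGEN Ovation biotin system for Affymetrix arrays. The deposited table holds log2 values, 1 per probeset and array, for 45101 probesets. Per the submitters' processing notes they were made with RMA, which corrects background, makes the arrays' distributions equal and summarizes the probes of each probeset; its version is not given in the sources used here. Present and absent calls of single probesets are not analysed here.

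Of the probesets, 34958 carry 1 gene symbol, 932 carry several and 9211 carry none; 64 probesets are array controls. Symbols were brought up to date through gene identifiers found in the reference gene table for 34754 probesets. Each of 18194 genes was read from 1 probeset, the one with the highest mean over the 12 arrays, 9012 genes having more than 1. A gene counted as measured in a comparison of 2 arrays when the higher value reached the floor of 3.86, the median of all values. Where 1 of the values lies near or under this floor, the size of the difference is a lower limit, and orders by size are those of the values as read. Array quality was described with the correlation between arrays, the median of 14 hybridization spike-in probesets, and the 5' minus 3' probesets of actin and Gapdh.

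With 1 array per group, responses to MALP-2 and differences between genotypes at 1 time are sizes without a test. Genes at least 2-fold above or below 0 h of their own genotype were counted, as were genes at least 2-fold apart between genotypes. For genes with a mean induction over 2 genotypes of at least 2-fold, the median difference in induction was taken. Its order-statistic 95% interval describes these arrays and not other mice. The medians of 28 gene lists, with 564 of 636 members measured, were computed in 25 comparisons each. Each median was ranked among those of 10000 random lists of the same size and matched on mean level in 10 bins, and this rank is given as a percentile. The lists are inflammatory cytokines, chemokines, immediate-early and AP-1 genes, the NF-kB family with its feedback inhibitors, the TLR and IL-1 receptor pathway, and secondary-response genes. They further are interferon-stimulated genes, prostaglandin, nitric oxide and arginine metabolism, antigen presentation and costimulation, glycolysis and hypoxia response, and cholesterol synthesis. LXR and PPAR targets, oxidative stress response, unfolded protein response, cell cycle, lysosome and phagocytosis, and ribosomal proteins follow. Markers of macrophages, neutrophils, B cells, T and NK cells, eosinophils and mast cells, dendritic cells, mesothelial and stromal cells, and erythroid cells were listed, with sex-linked genes and the genes flanking Irak2 and Irak1.

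Genotype differences over the stimulated times were tested with limma on the 9 arrays of 2, 4 and 8 h, with genotype and time as additive factors. This left 4 residual degrees of freedom (prior 4.72, prior SD 0.167 log2) for 10695 genes with a mean at or above the floor. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. A p-value of this fit weighs a difference against its constancy over the 3 times, not against the spread between mice. Calls of list members are adjusted over all genes, and for some lists and contrasts the calls adjusted over the list alone are given beside them. Data were also simulated from the mean of each gene at each time, with noise drawn from the fitted prior, so they obey the model. In them 89 of 100 genes shifted by 1 log2 and 100 of 100 shifted by 2 log2 were called, with 3 false calls. Of simulated lists of 25 genes, 7.0% without a shift and 100% with a shift of 0.5 log2 fell outside the 2.5th to 97.5th percentiles.

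These comparisons, the lists and most alternatives were set before the data were examined. Afterwards 3 things were added, because the 0 h array of the double knockout stood apart. Double-knockout responses were also computed against the mean of the wild-type and IRAK2-knockout 0 h arrays, called the substitute baseline. A value against it holds any constant difference of genotype or array besides the response to MALP-2. The floor and the probesets were also chosen from the other 11 arrays, and limma was also fitted to those 11. Also added was a limma fit of genotype slopes on log2 time over the 9 stimulated arrays, with 2 residual degrees of freedom, which tests whether a difference changed from 2 to 8 h. On simulated data it called 81 of 100 slopes of 1 log2 per doubling of time and 99 of 100 slopes of 2, with 13 false calls.

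The rule for named genes was also set in advance. It takes Irak1 and Irak2, then the 10 genes with the largest mean rise and fall over 2, 4 and 8 h in wild type (5 in each knockout) among those at least 2-fold changed the same way at all 3 times. For each genotype contrast it takes the 10 highest and 10 lowest called genes, and for IRAK2 knockout against wild type the 5 genes of each direction whose difference moved most from 2 to 8 h. From each list it takes up to 4 members with the largest differences or responses, and for markers the highest members. Genes called by the slope fit are named in addition. Alternatives tried were quantile normalization or median centring on top, other probeset and floor choices, 1.5-fold and 4-fold thresholds, other choices of induced genes, random lists not matched on level, and other sets of arrays or variance models in limma. The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.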

Results

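Macrophages recruited to the peritoneum with thioglycollate were exposed for 0, 2, 4 or 8 h to MALP-2, a lipopeptide sensed by TLR2 with TLR6. The cells came from wild-type mice, from mice without the kinase IRAK2, and from mice without both IRAK1 and IRAK2. The comparisons ask how much of the transcript response to MALP-2 needs IRAK2, and what is left when IRAK1 is missing too. The Irak2 probeset read 6.21, 6.69, 6.29 and 5.77 over time in wild type, 5.63, 5.51, 4.71 and 4.65 in the IRAK2 knockout and 3.53, 5.19, 4.61 and 5.09 in the double knockout. Over the stimulated times it was lower by -1.29 (adjusted p 0.025) and -1.28 (adjusted p 0.0011) log2 than in wild type. The 4 Irak1 probesets of the stimulated double-knockout arrays averaged -1.22, -0.66, -0.25 and -0.24 against wild type. Where these probes lie relative to the deleted segments is not given in the sources used here.

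MALP-2 left wild-type macrophages with abundant transcripts for interleukins, neutrophil-attracting chemokines and inhibitors of their own NF-kB signalling. Transcripts of the chemokine receptor Cxcr4 and of the signalling gene Rgs2 were scarcer at the same times. Il1b, which encodes interleukin 1 beta, read 8.42 log2 above its 0 h level on average over 2, 4 and 8 h (3.90 at 0 h, near the floor, then 12.33, 12.33 and 12.29). Cxcl3, Cxcl1 and Cxcl2, whose products recruit neutrophils through CXCR2, averaged 7.46, 7.27 and 6.69 above 0 h. Lcn2, whose product withholds iron from bacteria, averaged 7.20 and was highest at 8 h (11.51). Tnf averaged 5.78, the fatty acid receptor gene Gpr84 5.56, the Ras activator gene Rasgrp1 5.39, the cyclooxygenase gene Ptgs2 5.34 and the formyl peptide receptor gene Fpr2 5.27. Acod1, which makes itaconate, averaged 4.88 and Clec4e, the receptor Mincle, 4.68 above 0 h. Times of the highest level differed. The nuclear receptor gene Nr4a3 read 3.88 at 0 h, then 8.73, 6.58 and 5.35, and the interleukin 12 subunit gene Il12b read 3.60, then 8.12, 7.23 and 5.63. Il6 read 3.47, then 6.36, 7.98 and 8.98, the scavenger receptor gene Marco 5.35, then 7.61, 9.27 and 11.01, and the prostaglandin E synthase gene Ptges 5.88, then 7.39, 8.76 and 10.01.

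Among genes below their 0 h level at all 3 times, Fbxo32, a ubiquitin ligase subunit, averaged -4.68 log2 and Rgs2, a brake on G protein signalling, -4.59. Cxcr4 averaged -4.20, Arhgap19 -3.89, the lysophosphatidic acid receptor gene Lpar6 -3.67 and the lysosomal transporter gene Slc46a3 -3.35. Bex1 averaged -3.28, the p53-induced gene Trp53inp1 -3.26, Tmem86a, a lysoplasmalogenase, -3.23 and the thrombin receptor gene Thbd -3.22. In all, 612, 607 and 571 genes were at least 2-fold above 0 h at 2, 4 and 8 h, and 869, 787 and 641 at least 2-fold below it. At all 3 times 340 genes were above and 307 below.

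The list medians of wild type above 0 h at 2, 4 and 8 h were 2.11, 2.44 and 2.03 log2 for cytokines and 1.26, 1.47 and 1.70 for chemokines. They were 2.15, 1.74 and 1.64 for the NF-kB family and its inhibitors and 1.57, 1.94 and 2.20 for secondary-response genes. All 12 of these medians were at percentile 100 of the matched random lists. In the NF-kB list the inhibitor gene Nfkbie read 5.69 at 0 h, then 10.72, 9.60 and 9.59, and Zc3h12a, which cuts cytokine messengers, 5.25, then 8.89, 8.41 and 7.98. Immediate-early genes had medians of 0.31, 0.42 and 0.40, the TLR pathway 0.36, 0.26 and 0.21 (Tlr2 7.89, then 11.40, 11.38 and 11.03), and antigen presentation 0.18, 0.32 and 0.41. Prostaglandin, nitric oxide and arginine genes had 0.22, 0.31 and 0.36. Interferon-stimulated genes had -0.19, 0.18 and 0.59, with Gbp2 at 6.37, then 8.67, 9.32 and 9.70. Oxidative stress genes had 0.01, 0.28 and 0.62, among them the mitochondrial dismutase gene Sod2 (9.75 at 0 h, 12.72 at 8 h). Cholesterol synthesis genes stood at 0.05, 0.83 and 0.17, with Hsd17b7 at 7.65, then 8.03, 9.56 and 9.03. Lists with negative medians included the cell cycle (-0.45, -0.27, -0.24), lysosome and phagocytosis (-0.25, -0.39, -0.57), LXR and PPAR targets (-0.34, -0.30, -0.46) and macrophage markers (-0.23, -0.31, -0.42). Fabp4, a PPAR target that binds fatty acids, read 12.02 at 0 h and 8.94 at 8 h, and the efferocytosis receptor gene Mertk 8.58 and 6.97. Medians were -0.21, -0.18 and 0.07 for glycolysis and hypoxia genes, -0.11, -0.22 and -0.26 for the unfolded protein response and -0.21, -0.09 and -0.03 for ribosomal proteins.

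Without IRAK2, macrophages reached nearly wild-type transcript levels of most induced genes at 2 h, but many cytokine and chemokine transcripts were far lower at 8 h. Il6 showed this most strongly, its transcripts being almost back at the 0 h level by 8 h. Il1b, Cxcl1, Ptgs2 and the interleukin 12 subunit gene Il12a followed. Acod1, Clec4e and Nfkbie stayed near wild-type levels at all 3 times. Il6 read 3.42 at 0 h, then 5.79, 4.82 and 3.75, and its difference from wild type moved by -4.65 log2 from 2 to 8 h. In the slope fit it was the 1 gene of 10695 whose difference changed with time, by -2.33 log2 per doubling of time (SE 0.16, adjusted p 0.024). An unadjusted p under 0.05 was given by this fit for 533 genes, about as many as that threshold passes without any change. Il1b read 4.16, then 12.22, 11.11 and 8.46, a move of -3.72 against wild type. Ptgs2 read 4.83, then 10.49, 9.57 and 7.11 (-3.12), Cxcl1 4.71, then 11.87, 10.77 and 9.07 (-3.08), and Il12a 4.16, then 6.30, 5.94 and 5.05 (-2.90). Ccl4 moved by -2.80, Ccl3 by -1.46, Tnf by -1.31, Lcn2 by -1.09, Cxcl3 by -1.05 and Cxcl2 by -0.95. Fpr2 moved by 0.02, Acod1 by -0.03 and Clec4e by 0.30. Upward moves, of which the slope fit called 0, were read for some genes repressed in wild type: Bex1 by 1.95, Dio2, which activates thyroid hormone, by 1.25, Cxcr4 by 1.20, Trp53inp1 by 1.06 and Rgs2 by 0.93. Elavl4, an RNA-binding protein gene, moved by 1.87, Narf by 1.62, the glycan-branching enzyme gene Gcnt1 by 1.57 and the endothelin receptor gene Ednrb by 1.53.

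**Figure D1:**
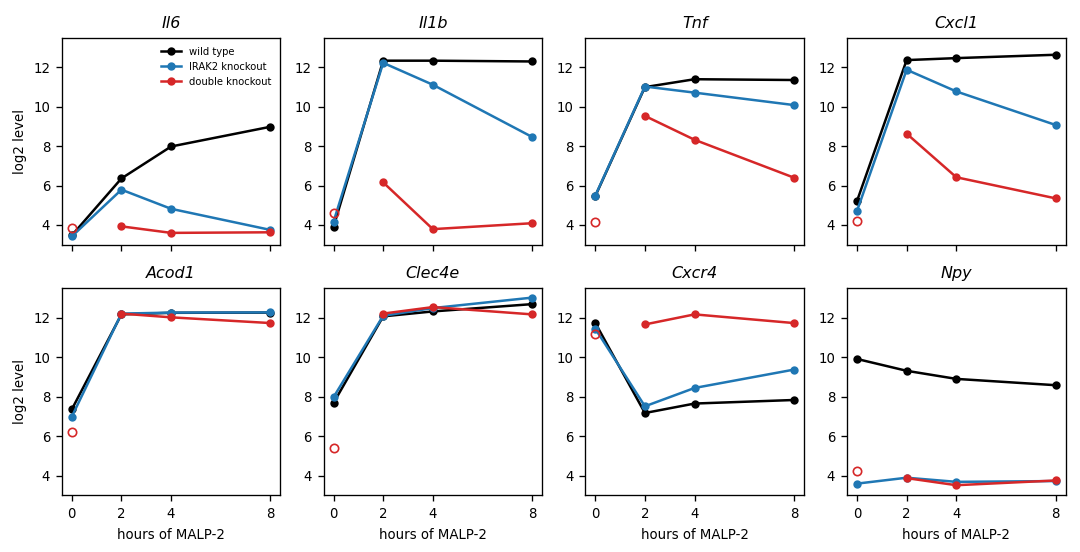
Log2 levels (vertical axis) of 8 genes against hours of MALP-2, 1 array per point, in wild type (black), IRAK2 knockout (blue) and double knockout (red), with the double knockout's 0 h array as an open marker. Il6 and Il1b of the IRAK2 knockout lie near wild type at 2 h (5.79 and 12.22) and far below it at 8 h (3.75 and 8.46).

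Adjusted over the list alone, the slope fit called 8 of 16 tested cytokines (Tnf, Il1a, Il1b, Il6, Il12a, Ebi3, Il18 and Inhba) and 7 of 17 chemokines (Ccl2, Ccl3, Ccl4, Ccl7, Cxcl1, Cxcl2 and Cxcl10) as falling further behind wild type with time. Ccl8 was called in the other direction. In the secondary-response list it called 5 of 22 (Cebpd, Marco, Il6, Cp and Ptx3), in the NF-kB list Zc3h12a and Socs3, and elsewhere Ptgs2, Ier3, 4 neutrophil markers (Camp, Csf3r, Mmp9 and Wfdc21) and 3 stromal markers (Col3a1, Dcn and Pdgfra). Of these only Il6 passed over all genes. In the other 20 lists no member passed either way.

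In the IRAK2 knockout 533, 492 and 368 genes were at least 2-fold above its own 0 h level at 2, 4 and 8 h, and 616, 578 and 340 below, with 224 above and 143 below at all 3 times. Cxcl3, Il1b, Lcn2, Cxcl2 and Cxcl1 stood furthest above it on average (6.85, 6.44, 6.44, 6.28 and 5.86). Fbxo32, Arhgap19, Rgs2, Lpar6 and Slc46a3 stood furthest below (-3.58, -3.48, -3.43, -3.07 and -3.06). Genes with a mean induction over both genotypes of at least 2-fold were compared. Their median induction without IRAK2 minus that of wild type was -0.13 log2 at 2 h (95% interval -0.15 to -0.10, 558 genes). It was -0.19 at 4 h (-0.23 to -0.16, 535 genes) and -0.45 at 8 h (-0.52 to -0.40, 442 genes). The share of these genes with a smaller induction than in wild type was 69.2%, 71.6% and 82.8%. Genes at least 2-fold apart from wild type numbered 53 at 0 h (17 higher, 36 lower), 60 at 2 h (29 and 31), 86 at 4 h (26 and 60) and 219 at 8 h (80 and 139).

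Some transcripts differed between IRAK2-knockout and wild-type cells at every stimulated time. Npy, which encodes neuropeptide Y, was strongly expressed in wild type and near the floor in the knockout, with or without MALP-2. The chemokine gene Ccl8 and the interferon-inducible gene Ifi202b were also low throughout, while the soluble pattern receptor gene Ptx3 and the growth factor gene Csf2 were lower after MALP-2. In limma 83 of 10695 genes were called, 38 lower and 45 higher than in wild type (260 and 295 with only these 2 genotypes in the fit, 6 and 0 with all 12 arrays), of which 24 and 19 at least 2-fold. Npy was lower by -5.17 log2 (adjusted p 9.43e-07), Ifi202b by -3.53 (4.61e-04), the galactosyltransferase gene B3galt6 by -3.15 (9.72e-04) and Ccl8 by -2.72 (1.15e-04). 1600014C10Rik (-2.30, 5.08e-05), Ptx3 (-2.05, 0.0038), Lancl2 (-1.97, 0.0015), the activin antagonist gene Fst (-1.49, 0.014), Cxcl14 (-1.38, 0.011) and the immunoglobulin gene Ighm (-1.35, 0.036) came next. Csf2 was lower by -1.21 (0.031), as was the arginine transporter gene Slc7a2 by -1.17 (0.021). Higher were Cap1, an actin regulator (2.46, 0.014), angiogenin (Ang, 2.07, 0.043), Ctr9 of the PAF1 complex (1.97, 0.0011, but -0.25 when probesets whose names end in _x_at or _s_at are left out), Slfn8 (1.80, 0.014), the peptide transporter gene Slc15a2 (1.38, 0.013), Slamf8 (1.37, 0.014) and the tyrosine-catabolism gene Fah (1.28, 0.015). Gpr176 (1.34, 0.043), Zfp994 (1.22, 0.014) and 2010315B03Rik (1.12, 0.043) were also higher. Il6 itself, whose gap was not constant, had -2.99 at an adjusted p of 0.10 (0.045 to 1 over the alternatives). Leaving out the 2, 4 or 8 h arrays left 8 lower and 0 higher, 6 and 0, and 9 and 5 calls, and 6 genes were called in each: Npy, Ifi202b, B3galt6, Ccl8, 1600014C10Rik and Lancl2. Of the 83 genes, 42 (50.6%) were at least 1.5-fold apart the same way at 0 h.

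By list, the cytokine median of the IRAK2 knockout against wild type was 0.02 log2 at 0 h and -0.17, -0.47 and -1.27 at 2, 4 and 8 h (percentiles 68.1, 0.01, 0 and 0). For chemokines it was -0.05, -0.06, -0.23 and -0.71, for the NF-kB list -0.03, -0.04, -0.16 and -0.42, and for secondary-response genes -0.02, -0.01, -0.18 and -0.40, each at percentile 0 at 8 h. Immediate-early genes had -0.04, -0.19 and -0.26 at the stimulated times, the TLR pathway -0.02, -0.11 and -0.23, and antigen presentation -0.08, -0.16 and -0.30. Calls over all genes (over the list alone in brackets) were 1 lower (6) for cytokines, 2 lower (6 lower, 1 higher) for chemokines, 2 lower (5) for secondary-response genes and 0 (1 lower) for the NF-kB list. The medians of interferon-stimulated genes were 0.13, 0.17, 0.12 and 0.44 (percentiles 99.9, 99.3, 95 and 100), and of 24 tested members 0 were called (1 higher). The antiviral gene Rsad2 read 6.26, 8.11 and 8.48 after MALP-2 in wild type and 7.32, 8.60 and 9.35 in the knockout, a difference of 0.81 (adjusted p 0.15). Cell cycle genes had 0.20, 0.39, 0.21 and 0.09, with 1 called higher (2 lower, 6 higher), the nucleotide reductase gene Rrm2 (0.79, adjusted p 0.025). Glycolysis and hypoxia genes had 0.17, 0.13, 0.18 and 0.22 with Bnip3 called (0.83, 0.046), cholesterol synthesis 0.09, 0.21, 0.18 and 0.32, and LXR and PPAR targets -0.09, 0.01, -0.04 and 0.15 with the scavenger receptor gene Cd36 called (0.76, 0.049). The remaining lists at 8 h were oxidative stress 0.22, unfolded protein response 0.22, prostaglandin, nitric oxide and arginine genes -0.21, lysosome and phagocytosis 0.09, and ribosomal proteins -0.04.

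**Figure D2:**
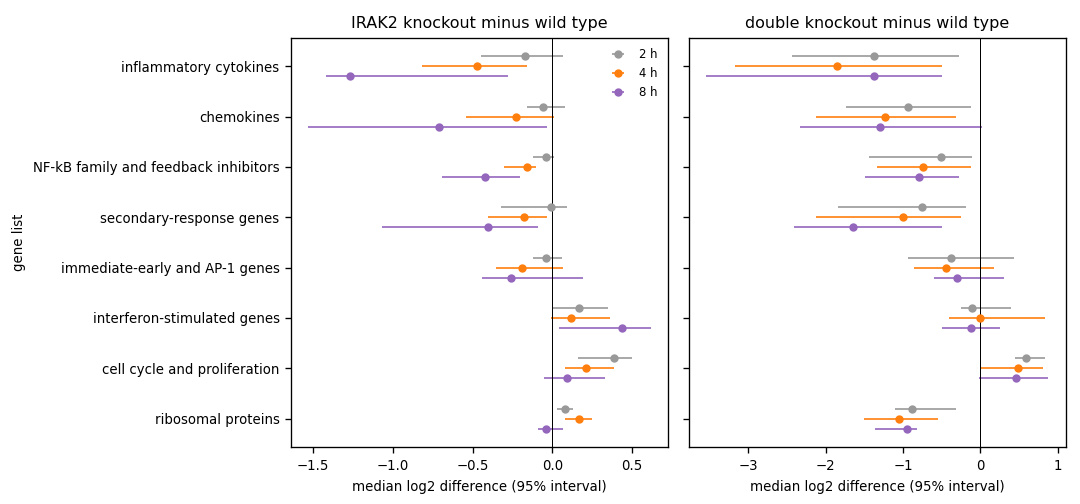
Median log2 difference from wild type (horizontal axis) of 8 gene lists at 2, 4 and 8 h, with bars for the 95% interval over the genes of each list, for the IRAK2 knockout (left) and the double knockout (right). The cytokine median of the IRAK2 knockout is -0.17 at 2 h and -1.27 at 8 h.

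In stimulated double-knockout macrophages most cytokine and chemokine transcripts were scarce compared with wild type. Lcn2 and Il6 stayed close to the floor throughout, and Il1b was only briefly raised. Tnf, Cxcl1, Cxcl2 and Cxcl3 were high at 2 h and much lower at 8 h. Acod1 and Clec4e nevertheless reached levels near those of wild type, as did Nfkbie at 2 and 4 h, while at 8 h Nfkbie was lower. Cxcr4, lower in stimulated wild-type cells than at 0 h, was abundant. Il1b read 6.16, 3.79 and 4.09 at 2, 4 and 8 h, lower than in wild type by -7.64 log2 (adjusted p 7.92e-05), and Lcn2 read 3.17, 3.36 and 3.42, all under the floor (-7.34, 3.04e-06). Cxcl1 read 8.63, 6.42 and 5.35 (-5.68, 1.88e-04), Cxcl3 6.99, 5.29 and 3.50 (-5.22, 3.90e-04), Ccl3 8.57, 7.96 and 7.38 (-4.75, 1.93e-05) and Ccl4 5.20, 4.84 and 4.91 (-4.49, 2.30e-04). Ptgs2 was lower by -4.53 (2.62e-04), the membrane-traffic gene Rab11fip1 by -4.15 (3.58e-04), Il6 by -4.05 (0.0017), Il12a by -3.60 (3.94e-04), Il1a by -3.55 (1.25e-05), Cxcl2 by -3.55 (0.0029) and Tnf by -3.16 (0.0015). Npy was as low as in the IRAK2 knockout (-5.22, 8.60e-07). Acod1 read 12.21, 12.02 and 11.73 (-0.24, adjusted p 0.18), Clec4e 12.21, 12.54 and 12.17 (-0.05, 0.84) and Nfkbie 10.58, 9.74 and 8.58 (-0.33, 0.21).

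Higher than in wild type were Hal, which degrades histidine (4.83, 8.91e-06), Cxcr4 (4.31, 3.03e-05), the chitinase-like gene Chil1 (3.95, 9.10e-06), Fbxo32 (3.90, 5.11e-06) and cathepsin E (Ctse, 3.44, 3.03e-05). Dio2 (3.08, 9.21e-05), Cep85 (2.98, 4.65e-05), Rgs2 (2.88, 1.18e-04), Plekhg1 (2.86, 8.91e-06) and the phosphodiesterase gene Pde1c (2.81, 6.91e-06) followed. Hal and Chil1 read 3.55 and 3.87 in wild type at 2 h against 8.95 and 8.18 in the double knockout. Cxcr4 read 11.66, 12.17 and 11.73 after MALP-2 (7.17, 7.65 and 7.83 in wild type). The macrophage mannose receptor gene Mrc1 was higher by 1.75 (2.09e-04), the monocyte chemokine receptor gene Ccr2 by 1.45 (4.17e-05) and Fabp4 by 1.46 (0.0061). The slope fit called 15 genes whose difference from wild type changed with time, 12 downwards and 3 upwards. Downwards were Cxcl2 (-2.20 per doubling of time, adjusted p 0.0085), Cxcl3 (-2.08, 0.018), Wfdc21 (-1.99, 0.018), Tnf (-1.74, 0.014), the collagen cross-linker gene Lox (-1.59, 0.014), Icosl (-1.55, 0.014), Ripor2 (-1.51, 0.042) and Il6 (-1.46, 0.041). Plpp1 (-1.40, 0.018), ceruloplasmin (Cp, -1.30, 0.026), Rasgrp1 (-1.29, 0.041) and Lmo4 (-1.29, 0.041) completed them. Upwards were Phxr4 (1.42, 0.026), the calcium-regulated factor gene Nfatc2 (1.39, 0.018) and Ndrg1 (1.29, 0.042; 0.14 without probesets ending in _x_at or _s_at).

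Over the 9 stimulated arrays 4465 genes were called, 1876 lower and 2589 higher (2360 and 2066 with arrays centred on their medians), of which 511 and 541 at least 2-fold, and 1963 in all 3 fits that leave out 1 time. Genes at least 2-fold apart numbered 1089 at 2 h (559 higher, 530 lower), 1525 at 4 h (796 and 729) and 1247 at 8 h (678 and 569). At 0 h the count was 6311 (1708 and 4603). The 0 h array of the double knockout correlated with the others at 0.764 to 0.804, while the other 11 correlated at 0.954 or more, and its spike-ins read 12.16 against 10.15 to 10.60 elsewhere. The stimulated double-knockout arrays had weaker 5' signal than the other 8, with actin 5' minus 3' values of -4.25, -4.68 and -3.87 against -3.72 to -3.18 and Gapdh values of -5.29, -5.90 and -4.36 against -3.84 to -3.42.

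**Figure D3:**
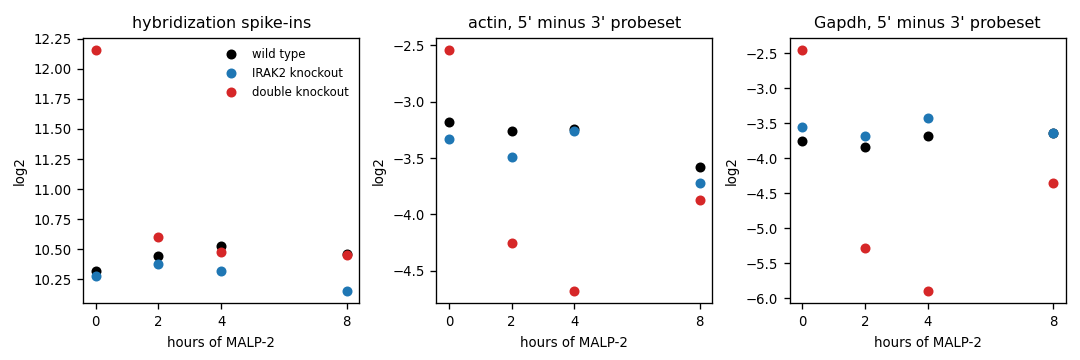
Median log2 level of the hybridization spike-ins and log2 5' minus 3' probesets of actin and Gapdh against hours of MALP-2, 1 point per array. The 0 h array of the double knockout has spike-ins at 12.16, and its 3 stimulated arrays have the lowest 5' minus 3' values.

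Against its own 0 h array the double knockout had 4193, 4410 and 4723 genes at least 2-fold higher and 1634, 1598 and 1620 lower, 3771 and 1191 of them at all 3 times. Against the substitute baseline it had 498, 540 and 397 higher and 705, 677 and 363 lower, 211 and 239 at all 3 times. That baseline comes from other genotypes, so values against it also hold constant differences of genotype or array. With that baseline Acod1, Clec4e, Chil1, Hal and Nfkbie stood furthest above it on average (4.82, 4.48, 4.34, 4.29 and 3.76). Rps9, Atp5g2, Ifi209, Fcor and Arhgap19 stood furthest below (-3.99, -3.73, -3.29, -3.18 and -3.05), Rps9 as read from a probeset ending in _x_at. Genes were then taken with a mean induction over both genotypes of at least 2-fold. With the double knockout's own 0 h array, these genes had median inductions of 0.26, 0.29 and 0.25 log2 in wild type and 2.7, 2.65 and 2.68 in the double knockout. The median difference in induction, double knockout minus wild type, was 2.42, 2.37 and 2.46 log2. With the substitute baseline it was -0.49 (95% interval -0.57 to -0.37), -0.38 (-0.51 to -0.28) and -0.77 (-0.96 to -0.66).

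Against wild type, 14 of 16 tested cytokines were called lower and 1 higher, and the list medians were -1.38, -1.85 and -1.37 log2 at 2, 4 and 8 h (-1.70, -2.46 and -2.67 with only members above the floor). Of 17 chemokines 15 were lower and 0 higher (-0.94, -1.23, -1.30). Of 25 NF-kB genes 15 were lower and 1 higher (-0.51, -0.74, -0.79), among them Socs3 (-3.17, adjusted p 2.59e-04), Zc3h12a (-2.81), Nfkb2 (-2.59) and Nfkbiz (-2.52). Of 22 secondary-response genes 16 were lower and 1 higher (-0.75 at 2 h and -1.64 at 8 h), including Marco (-3.31), Il12b (-3.25), Ptx3 (-2.94) and Fpr2 (-2.82). Each of these 12 medians was at percentile 0. Calls over the list alone were the same in number for cytokines, chemokines and secondary-response genes and 16 lower and 1 higher for the NF-kB list. Immediate-early genes had 11 lower and 6 higher of 23 (12 and 7 over the list alone), with Nr4a3 lower (-2.49) and Klf4 (1.61) and Fos (1.59) higher, and medians of -0.38, -0.45 and -0.30. The TLR pathway had 8 lower and 7 higher of 26 (Tlr7 -1.95, Cd14 -1.85, Tlr2 -0.92). Prostaglandin, nitric oxide and arginine genes had 7 lower and 1 higher of 12, and antigen presentation 7 and 1 of 23 (Icosl -2.99, Cd40 -1.79). Interferon-stimulated genes had 5 lower and 5 higher of 24, with Mx1 lower (-1.66) and Rsad2 (1.39) and Oasl2 (1.17) higher. Cell cycle genes had 2 lower and 14 higher of 25 (2 and 19 over the list alone) and medians of 0.59, 0.49 and 0.46, with cyclin D1 (Ccnd1) at 1.82 (2.02e-05) and cyclin D2 (Ccnd2) at -2.49.

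Ribosomal protein genes were called lower in 16 of 17 cases (17 over the list alone), with medians of -0.88, -1.05 and -0.95 at percentile 0. Genes counted as without a response to MALP-2 when they stayed under 0.5 log2 from 0 h at all times in wild type and the IRAK2 knockout. Of 4476 such genes tested, 1351 (30.2%) were called in this contrast, against 4465 of all 10695. Among the genes without a response the difference rose with genomic gene length (Spearman correlation 0.33). Rps9 had -3.48 (-0.38 without probesets ending in _x_at or _s_at), Rps6 -1.63, Rps19 -1.53 and Rpl8 -1.35. Cholesterol synthesis had 6 lower and 1 higher of 20 (-0.26, -0.56 and 0.00), glycolysis and hypoxia 3 lower and 6 higher of 22, and LXR and PPAR targets 3 and 4 of 19 (Cpt1a 1.74, Apoe -1.46). Oxidative stress genes had 6 and 6 of 18 (Slc7a11 -1.54, Sod2 -1.10), the unfolded protein response 4 and 5 of 20, and lysosome and phagocytosis 4 and 4 of 23.

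With both kinases missing, 10 of 16 tested cytokines and 14 of 17 chemokines were called lower than with IRAK2 alone missing, and 1 and 2 higher. Lcn2 and Il1b were among the genes with large differences, while Il6 differed by -1.86, -1.22 and -0.12 at 2, 4 and 8 h. The guanylate-binding protein gene Gbp2b was induced in the IRAK2 knockout and near the floor in the double knockout. Ifi202b was low in the IRAK2 knockout and high in the double knockout. Lcn2 was lower by -6.64 log2 (adjusted p 8.16e-06), Il1b by -5.92 (2.96e-04), Cxcl3 by -4.73 (7.35e-04), Gbp2b by -4.32 (9.25e-07), Ccl3 by -4.14 (4.08e-05) and Cxcl1 by -3.77 (0.0013). Rps9 had -4.34 (9.25e-07; -0.38 without the probesets named above), Plet1 -4.02 (2.93e-04), the ATP synthase subunit gene Atp5g2 -3.64 (4.75e-04) and the liprin gene Ppfia3 -3.35 (8.39e-06). Tnf was lower by -2.52 (0.0047) and Il6 by -1.07 (0.23). Higher were Hal (4.67, 1.62e-05), Ifi202b (4.42, 1.66e-05), Chil1 (4.16, 1.02e-05), Cep85 (3.87, 1.66e-05), Ctse (3.67, 2.67e-05), Cxcr4 (3.42, 9.73e-05), Plekhg1 (3.25, 8.16e-06) and Fbxo32 (3.14, 1.62e-05). Pde1c (2.82, 8.39e-06) and the lysosomal channel gene Mcoln3 (2.80, 1.52e-04) followed. Csf2 (-0.08, 0.75), Slc7a2 (-0.13, 0.57) and Npy (-0.06, 0.78) differed little.

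In this contrast 4236 genes were called, 1817 lower and 2419 higher (2201 and 1964 with arrays centred on their medians), of which 460 and 413 at least 2-fold, and 1506 in all 3 fits that leave out 1 time. Genes at least 2-fold apart numbered 6198 at 0 h (1673 higher, 4525 lower) and 995 (429 and 566), 1414 (678 and 736) and 861 (465 and 396) at 2, 4 and 8 h. The median difference in induction was 2.47, 2.44 and 2.62 log2 with the double knockout's own 0 h array. With the substitute baseline it was -0.31 (95% interval -0.44 to -0.23), -0.19 (-0.32 to -0.07) and -0.43 (-0.57 to -0.27). List medians were -0.82, -1.17 and -0.24 for cytokines (10 called lower, 1 higher), -0.79, -1.04 and -0.51 for chemokines (14 and 2) and -0.75, -0.76 and -0.75 for secondary-response genes (13 and 1). They were -0.39, -0.44 and -0.37 for the NF-kB list (13 and 2) and -0.43, -0.77 and -0.27 for cholesterol synthesis (13 and 1). Ribosomal proteins had -0.90, -1.05 and -1.03 (16 and 0).

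Among cell identity genes, Csf1r, the receptor for the macrophage growth factor, read 12.82 to 13.31 in all stimulated arrays, and Lyz2 and Mpeg1 read above 12 in each. Macrophage markers had medians of 0.10, 0.11 and 0.08 in the IRAK2 knockout (1 called higher, 2 over the list alone) and 0.12, 0.24 and 0.24 in the double knockout against wild type (4 lower and 5 higher). Neutrophil markers had -0.06, 0.00 and -0.23 without IRAK2 (0 of 6 called, 2 lower and 0 higher over the list alone). In the double knockout they had -0.08, -0.09 and -0.20 (4 of 6 lower, among them S100a8 at -1.55). B cell markers had -0.12, -0.21 and -0.36 without IRAK2 (Ighm called, 2 lower and 0 higher of 6 over the list alone). In the double knockout they had -0.01, -0.07 and -0.28. At 8 h the medians without IRAK2 and in the double knockout were -0.05 and -0.03 for T and NK cells and -0.08 and -0.16 for dendritic cells. Of 6 tested dendritic cell markers, 3 were lower and 0 higher without IRAK2 over the list alone. For eosinophils and mast cells the medians were -0.04 and 0.24 (Siglecf 1.19 in the double knockout). They were -0.14 and 0.03 for mesothelial and stromal cells (Krt8 1.40) and 0.06 and 0.09 for erythroid cells. Sex-linked genes had 0.10 and 0.13, with the Y-linked Eif2s3y between 8.83 and 10.69 and Xist between 4.00 and 5.62 in all arrays. Genes flanking Irak2 had 0.02 and 0.14 and those flanking Irak1 0.03 and -0.02, with 0 called without IRAK2. In the double knockout 8 of 25 and 10 of 22 were called, where 4465 of all 10695 tested genes were called.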

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

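The slope fit, its splits, the spike-in, swap and 5' tests, and the comparison of genes induced without IRAK2 were chosen after the result was seen. So was the substitute baseline, on which the opposite directions and the 498 genes above it at 2 h in the double knockout rest. The other tests here were set earlier.

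In the slope fit, 1 gene differed in its time course between IRAK2-knockout and wild-type cells after adjustment, Il6 with -2.33 log2 per doubling of time, and 15 genes differed between double-knockout and wild-type cells. The 6 arrays of a contrast allow 10 splits into 3 against 3, too few for a share under 0.05. The splits do not keep the 3 times balanced, so some of them mix differences of genotype and time. For the IRAK2 knockout 2 of the 10 splits gave as many genes as the real one, and the highest other split called 10 where the real one called 1. What gave the 10 calls of that split was not identified, and the splits cannot tell whether the real call arose by chance. The single call rests on a fit with 2 residual degrees of freedom, so it carries little weight. For the double knockout 1 split, the real one, gave 15, and the highest other gave 0. In the additive fit the real splits called 83, 4465 and 4236 genes for IRAK2 knockout against wild type, double knockout against wild type and double knockout against IRAK2 knockout. In each case 1 split of 10, the real one, gave as many, and the highest other gave 0.

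At least 1.5-fold from 0 h at all 3 times, but in opposite directions, were 15 genes of the double knockout (substitute baseline) and wild type. For the double knockout, 0 h here means the wild-type and IRAK2-knockout 0 h arrays. A constant difference of genotype or array can therefore look like an opposite response. The difference was not tested. Higher in the double knockout and lower in wild type were Ankrd12, Arnt2, Dmpk, Efr3b, Galc, Itgb3, Krt8, Mcoln3, Plxna2 and Zranb3, for example the lysosomal channel gene Mcoln3 (1.13, 1.54 and 1.20 against -1.10, -2.32 and -2.03) and the integrin gene Itgb3 (1.15, 1.12 and 1.65 against -0.79, -1.39 and -1.54). Lower in the double knockout and higher in wild type were Cxcl13, Gbp2b, Ms4a6c, Pirb and Timp1, for example the B cell chemokine gene Cxcl13 (-1.23, -1.56 and -2.89 against 0.81, 0.99 and 1.20) and the protease inhibitor gene Timp1 (-0.73, -1.25 and -0.63 against 1.79, 1.84 and 1.86).

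Among 9160 probesets without a gene name, which no comparison uses, 15 were at least 4-fold above 0 h at 2, 4 and 8 h in wild type. Their median in the IRAK2 knockout against wild type was -0.18 log2 at 2 h and -0.86 at 8 h, and 1 of the 15 was at least 2-fold lower at 2 h and 6 at 8 h.

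The hybridization spike-ins, also outside the comparisons, were 1.76 log2 higher on the 0 h array of the double knockout than the mean of the other 11 (10.4), whose largest deviation was 0.25. Spike-ins are added in a fixed amount, and normalization lifts them where the sample gives little signal, so this shift is consistent with little target on that array. As a test of a swap, 0 of the other 11 arrays had a highest correlation under 0.9, each correlating at 0.984 or more with its nearest array. These correlations do not use the labels and would be the same after a swap, so they cannot decide this. On the 0 h array of the double knockout the 5' minus 3' values of actin and Gapdh (-2.54 and -2.45) were the highest of all 12 arrays. This goes against degraded RNA unless the narrow spread of that array (SD 1.72 against 2.01 to 2.04) shrank them. A poor labelling reaction and a difference between cells of this genotype without MALP-2 stay open, since 1 array holds this group.

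Over the stimulated times the double knockout had lower levels of MALP-2-induced genes and broad differences elsewhere. Genes induced in the IRAK2 knockout (533, 492 and 368 at 2, 4 and 8 h) had double-knockout minus wild-type medians of -0.73, -0.92 and -1.08. These were at percentile 0 of random lists matched on level, whose medians were 0.07, 0.07 and 0.09. The random lists were not matched on length or probe position, and ribosomal protein genes also stood at percentile 0. The comparison therefore cannot decide whether weaker 5' signal is the whole cause for the induced genes. Outside the induced genes, 1351 of 4476 tested genes without a response (30.2%) were called, 168 of these at least 2-fold, against 7 for the IRAK2 knockout. Over all 10695 tested genes 4465 and 83 were called. The genes without a response were chosen as stable on the wild-type and IRAK2-knockout arrays, which can lower the count for the IRAK2 knockout. In the control probesets, 6 of 6 values of actin and Gapdh lay below those of all 8 other arrays. The difference also rose with genomic gene length (Spearman correlation 0.33 over 4467 genes, median -0.13 in the 894 shortest genes and 0.20 in the 894 longest). Weaker 5' signal is a candidate cause of the broad differences on the control values alone. Genomic length is not transcript length, so the trend leaves transcript size bias a candidate that was not measured directly. Loss of both kinases stays open for the induced genes, as does any handling of these 3 arrays apart from the rest.

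The gap of induced genes between IRAK2-knockout and wild-type cells widened from 2 to 8 h. A quality loss of the knockout's 8 h array that acts alike on genes of similar level is argued against. The test used 498 genes at least 2-fold above the substitute baseline at 2 h in the double knockout, chosen without the arrays compared. They widened by a median of -0.17, against -0.05 for matched random lists (lowest -0.10), at percentile 0. These lists were not matched on length or probe position, so a loss that acts unevenly on transcripts stays open. As a test of scaling between arrays, the cytokine list widened by a median of -0.58 and -0.60 under quantile normalization or median centring (-0.68 without them). RMA had already made the arrays' distributions equal, so these settings could change little and cannot decide on scaling. Weaker 5' signal of that array may contribute: 1 of 2 values lay below all wild-type arrays (actin -3.72 against -3.58; Gapdh was not lower), short of the 2 of 2 set as the bound, yet it is kept open because 1 array gives no spread. A shorter-lived response without IRAK2 stays a hypothesis that rests on list medians and on the slope fit. That fit leaves 2 residual degrees of freedom, and its call of Il6 carries little weight. Its calls over the lists alone were not put to the splits.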

How the results depend on the processing

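The substitute baseline, the floor and probeset choice without the double knockout's 0 h array, the fit on 11 arrays and the slope fit were chosen as tests after the result was seen; the other alternatives were set earlier. No paired analysis was possible because each group holds 1 array and the labels carry no replicate numbers; time is a factor in the limma fits.

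The double knockout's response depends on its 0 h array. Against the substitute baseline 498, 540 and 397 genes were at least 2-fold higher and 705, 677 and 363 lower at 2, 4 and 8 h. These counts hold constant differences of genotype or array besides the response. The median difference in induction, read with that baseline and under the same limit, turned to -0.49, -0.38 and -0.77 against wild type. Against the IRAK2 knockout it turned to -0.31, -0.19 and -0.43. Without subtracting 0 h arrays it was -0.10, -0.12 and -0.03, and -0.08, -0.08 and 0.09. With genes chosen on wild type alone it was -0.17, -0.23 and -0.50 against wild type, and with genes chosen on the IRAK2 knockout alone -0.05, -0.16 and -0.09 against that knockout. It stayed positive with genes chosen on the double knockout alone (2.12, 2.05 and 2.04; 2.06, 2.02 and 2.03), a mean induction of at least 2 (2.96, 3.11 and 3.41; 3.11, 3.30 and 3.83), the mean of all probesets of a gene (1.88, 1.93 and 2.04; 1.97, 2.03 and 2.31), quantile normalization (2.29, 2.21 and 2.32; 2.35 and 2.31 at 2 and 4 h) and median centring (1.56, 1.64 and 1.84; 1.80, 1.86 and 2.22). Median centring subtracts -1.08 from that array, which raises it, and subtracts -0.03 to 0.21 from the others. It gave 1836, 1769 and 1845 induced and 10339, 10642 and 10931 repressed genes, and 12842 and 12683 genes 2-fold apart from wild type and from the IRAK2 knockout at 0 h. The floor at the 75th percentile gave 1031, 975 and 1042 repressed genes.

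For the IRAK2 knockout against wild type, the median difference stayed negative in all 11 settings tried. It moved to -0.17, -0.26 and -0.53 with genes chosen on wild type alone, -0.07, -0.12 and -0.31 on the knockout alone, -0.16, -0.33 and -0.58 at a mean induction of at least 2, -0.16 and -0.24 at 2 and 4 h with quantile normalization, and -0.22 at 2 h with median centring.

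At 1.5-fold, 1197, 1264 and 1274 genes were induced and 2278, 1868 and 1593 repressed in wild type, 1137, 1130 and 886 and 1737, 1457 and 1021 in the IRAK2 knockout, and 3132, 3084 and 3032 repressed in the double knockout. Genes apart numbered 306, 381, 542 and 1007 at 0, 2, 4 and 8 h for the IRAK2 knockout against wild type. At 2, 4 and 8 h they numbered 3218, 3870 and 3377 for the double knockout against wild type and 3065, 3793 and 2986 against the IRAK2 knockout. At 4-fold, 208, 190 and 191 were induced and 110, 130 and 117 repressed in wild type, 186, 133 and 108 and 57, 69 and 49 in the IRAK2 knockout, and 2108, 2127 and 2337 and 466, 425 and 518 in the double knockout. Genes apart at 0, 2, 4 and 8 h were then 11, 9, 10 and 31 for the IRAK2 knockout against wild type, 2781, 147, 220 and 213 for the double knockout against wild type, and 2754, 120, 181 and 103 against the IRAK2 knockout.

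The mean of all probesets of a gene gave 498, 474 and 408 repressed genes in wild type, 336, 324 and 217 in the IRAK2 knockout and 1041 and 1032 at 2 and 4 h in the double knockout. Genes 2-fold apart were 30, 46 and 120 at 0, 4 and 8 h for the IRAK2 knockout against wild type, 689, 901 and 763 for the double knockout against wild type and 601, 849 and 474 against the IRAK2 knockout. In limma this setting gave 1474 genes higher in the double knockout than in the IRAK2 knockout, and the slope fit then called 7 genes for the double knockout against wild type.

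With all 12 arrays limma called 6 lower and 0 higher for the IRAK2 knockout against wild type, 734 and 439 for the double knockout against wild type, and 650 and 367 against the IRAK2 knockout. With the 11 arrays other than the 0 h array of the double knockout the first contrast had 75 and 74, with only its own 2 genotypes 260 and 295, and without probesets ending in _x_at or _s_at 26 higher. Requiring 2-fold left 24 and 19, 511 and 541, and 460 and 413. Leaving out 1 time gave 6 to 9 lower and 0 to 5 higher, 885 to 1766 and 1250 to 2281, and 699 to 1887 and 892 to 2120, the lowest of the last 4 ranges without the 4 h arrays.

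Directions of single genes turned without probesets ending in _x_at or _s_at for Ctr9 (-0.25 and -0.18 for the IRAK2 and the double knockout against wild type) and Rps9 (-0.01 for the IRAK2 knockout). With all 12 arrays they turned for Arhgap19 (-0.50), Mertk (-0.44) and Thbd (-0.40) of the double knockout against wild type and for Mertk (-0.01) and Thbd (-0.67) against the IRAK2 knockout. The dendritic cell markers of the double knockout against the IRAK2 knockout at 2 h turned from -0.21 to 0.01 with the mean of all probesets and without probesets ending in _x_at or _s_at. The slope of Il6 between IRAK2 knockout and wild type was -2.29 to -2.33 in the 4 alternatives (adjusted p 0.017 to 0.038).

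Of 5244 values of the named genes under the alternatives, 4886 stayed on the same side of an adjusted p of 0.05, 263 no longer passed, 87 newly passed and 8 turned direction. Some values could not be given. The floor at the 75th percentile removed 27 named genes from the fit, among them Il6, Npy, Ptx3, Csf2, B3galt6, Hal, Chil1, Ctse and Fbxo32. Leaving out probesets ending in _x_at or _s_at left none for Ifi202b, S100a8, Arhgap19 and Xist. With the mean of all probesets Ccr2, Ighm, Pde1c and Xist lay below the floor. The fit with only 2 genotypes lacked 7 values, such as Npy in the contrast of the knockouts.

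The medians of cytokines and chemokines in the differences from wild type left their 95% interval over genes in 0 of 84 values, but these intervals are wide. With only members above the floor the 8 h cytokine median of the double knockout went from -1.37 to -2.67 and the 8 h chemokine median of the IRAK2 knockout from -0.71 to -1.21. With the mean of all probesets the 8 h cytokine median of the IRAK2 knockout went from -1.27 to -0.84. Of the 2100 other list medians 20 left that interval, mostly with median centring or with only members above the floor. The dendritic cell markers given above were the 2 that turned. Of 364 list percentiles, 22 newly lay in the outer tails and 5 no longer did, all with random lists not matched on level. The intensity trend, no floor, and the floor and probeset choice from 11 arrays turned no direction.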

Other observations

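The test on differences present without MALP-2 and the test on genes beside Irak2 were set before their results were seen; the length correlation for the IRAK2 knockout and the reading of single genes below were chosen after.

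Some of the differences between IRAK2-knockout and wild-type cells may come from the mice's background and not from the loss of IRAK2 during the response. Of the 83 genes called in limma, 50.6% differed at least 1.5-fold the same way without MALP-2, Npy among them (3.59 at 0 h against 9.91). As a test of genes carried along with the targeted Irak2 locus, 106 tested genes among the 100 nearest on either side were counted, and 0 were called. Only 0.81 were expected, so 0 calls shows no excess in this window but cannot exclude carried genes. Genes further away on the chromosome were not tested. Ifi202b was near the floor in the IRAK2 knockout (4.21 at 0 h) and high in the double knockout (9.95), while Npy was low in both. The strains of the mice are not given in the sources used here, so the background itself was not tested.

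Length trends ran in opposite directions in the contrasts with wild type. Across 4467 genes without a response, the IRAK2 knockout minus wild type fell with genomic length (Spearman correlation -0.257), while the double knockout minus wild type rose (0.33). RNA quality that differs between arrays could give such trends in either direction, and no array was repeated. The medians of the ribosomal protein list against wild type were -0.88, -1.05 and -0.95 in the double knockout.

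Acod1, Clec4e and Nfkbie reached similar levels in all 3 genotypes at 2 h (12.17, 12.21 and 12.21 for Acod1), whereas Lcn2 and Il6 of the double knockout stayed within 1 log2 of 0 h. At 8 h Nfkbie of the double knockout was below wild type. A part of the response that needs neither kinase is a candidate explanation, and the effect on these genes of the weaker 5' signal of the double-knockout arrays (6 of 6 values) was not tested. Whether these genes differ as a group from the others was not tested.

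The median of interferon-stimulated genes without IRAK2 was above wild type by 0.13, 0.17, 0.12 and 0.44 at 0, 2, 4 and 8 h, but at 4 h it did not stand out from random lists (percentile 95). No single gene of that list passed the adjustment over all genes.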
